A study of Mus musculus with 6 samples.

How the data were processed

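The data are RNA-seq libraries from mouse epididymal white adipose tissue, 3 from wild type and 3 from Prmt5 knockout. Genotype and replicate number were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol, polyA RNA was enriched on beads and libraries were sequenced on an Illumina HiSeq. The submitters' processing notes name TopHat2, HTSeq 0.6.1 and the genome build mm10, with no role or order. The strand setting, the annotation and the treatment of reads shared between genes are not given in the sources used here.

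The authors deposited one table of 14291 genes with raw counts per gene and library. Per the file headers it also holds the authors' log2 RPKM values and a log2 fold change, with the authors' p-value and adjusted p-value for each gene. The deposited exonic length of each gene equalled the length of its merged exons in the same table. Rows below a low expression level had been left out: the least third-highest CPM of a gene was 0.606, so filterByExpr removed 0 genes and the alternative without a filter moved nothing. The counts were the values tested, and the log2 RPKM values were used only to learn the unit. No column of values was left without a sample. Total counts per library ran from 17489530 to 26403882, so a gene at 1 CPM rests on few reads per library and low genes are the least precise.

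Counts were tested with edgeR 4.0.16 in R 4.3.3. TMM factors (1.086, 0.9726 and 1.047 in wild type, 1.17, 0.8975 and 0.8607 in knockout) scaled the libraries, filterByExpr was applied with genotype, and glmQLFit and glmQLFTest compared knockout with wild type with genotype as the only term. Adjusted p-values are Benjamini-Hochberg values over 14291 genes, and a gene was called at an adjusted p under 0.05. The biological coefficient of variation was 0.435. CPM values are TMM-scaled counts relative to the library total, and standard errors of log2 fold changes were taken from the fold change and the F statistic. The test, the gene lists, the naming rule and the first group of other settings named below were fixed before the data were examined.

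The deposited p-values were compared with edgeR fits that hold a batch term. The grouping of replicate 1 against replicates 2 and 3 matched them with a median absolute log10 ratio of 8.3e-14, while the other groupings and the fit with no batch term gave 0.115 to 0.269. The submitters' name for the deposited values holds the word batch, but neither it nor the labels say what this grouping was. It is called a batch here. The batch-term fit had a biological coefficient of variation of 0.32 and 3 residual degrees of freedom, against 4 with genotype only.

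The 37 gene lists covered PRMT5 partners, lipid and energy metabolism, stress and inflammatory responses, the cell types of adipose tissue and of tissue beside it, and the chromosomal neighbours of Prmt5 and Adipoq. The 33 lists with at least 3 tested members were tested with camera (limma 3.58.1) at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with the correlation estimated per list and with fry. Epididymis and testis, red blood cell, mitochondrially encoded and sex-linked gene lists had too few members for a test. Members were also adjusted over the list alone. A listed symbol missing from the table was matched through older symbols of the same gene only.

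Genes named in the text were Prmt5, 15 genes named whatever their values, up to 4 members with the smallest p from each list described, and the 10 highest and 10 lowest log2 fold changes among called genes. The last part took genes with a mean CPM of at least 1 and no overlap between genotypes, leaving out unnamed gene models and pseudogenes. The genotype-only fit gave 0 genes under the last part, so that part was applied to the batch-term fit, after the data were seen. Genes named outside this rule are said to be chosen after their values were seen. Some genes that this rule takes are not reported here.

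The settings fixed in advance were RLE size factors, no filter and a strict filter (at least 10 counts in every library of a genotype), DESeq2 1.42.0, limma-voom, the replicate number as a block, an adjusted p under 0.1 or with at least a 2-fold change, and each library left out in turn. A pseudocount did not apply to counts. Added after seeing the data were the batch term, the batch term with each library left out, replicates 2 and 3 alone, and loess offsets (span 0.5) that remove each library's trend with exonic length and GC content, with and without the batch term. GC content came from GENCODE M21 exons by gene symbol and was known for 13786 genes (96.5%). Where a fit leaves 1 library of a genotype in a batch beside the other genotype, that library is assumed to vary like the others. Where the batch-term fit leaves out replicate 1 of a genotype, the other replicate 1 library is alone in its batch. It then adds nothing on genotype, and such a fit comes close to that of replicates 2 and 3 alone.

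The tests were tested on simulated data, with 50 genes changed at each fold. Counts were drawn from the real means, the library sizes and each fit's own dispersions. Genes varied independently and no batch effect was simulated, so recovery in the real libraries may differ. Genotype only, over 14227 genes, recovered 4% of genes changed 2-fold, 42% at 4-fold, 90% at 8-fold and 100% at 16-fold. With the batch term, over 14252 genes, recovery was 28%, 84%, 98% and 100%. Called though unchanged were 3 genes with genotype only and 10 with the batch term.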

Results

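PolyA-selected RNA from fat labelled epididymal white adipose tissue was sequenced for 3 wild-type and 3 Prmt5 knockout libraries. That is the visceral depot along the epididymis, and sex-linked transcripts, given below, put the label in doubt. Prmt5 encodes an enzyme that places symmetric dimethyl marks on arginines of histones, spliceosomal proteins and other targets, and the wild-type mice carried floxed Prmt5 alleles. The comparison asks which genes differ in expression between fat tissue with and without the deletion. The labels write the knockout as Prmt5AKO without expanding it and name neither a Cre driver nor the cell type of the deletion. Prmt5 transcript left in the knockout may come from cells that kept the gene, and changes in other transcripts are those of the whole tissue. Total counts over the 14291 genes analysed were 20746401, 26403882 and 25660998 in wild-type replicates 1 to 3. They were 17489530, 24454163 and 23494089 in knockout replicates 1 to 3. Nothing in the labels says that the libraries of one genotype came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Expression is given in CPM (library-size-normalised counts), scaled by edgeR's TMM factors, as mean ± SD over the 3 libraries of a genotype, wild type first. Fold changes are knockout over wild type on the log2 scale.

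The libraries also differed in ways that genotype did not set. The first principal component held 61.8% of the variance of log2 CPM. It placed wild-type replicate 1 (score -78.2), wild-type replicate 3 (-45.7) and knockout replicate 1 (-53.3) apart from wild-type replicate 2 (27.3), knockout replicate 2 (64.9) and knockout replicate 3 (85). The deposited fold changes and p-values matched, with a largest log2 difference of 8.33e-15, an edgeR quasi-likelihood fit that holds a 2-level batch term parting replicate 1 of both genotypes from replicates 2 and 3. That fit, called the batch-term fit here, was added after the data were seen. Its values stand beside those of the planned genotype-only fit.

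**Figure D1:**
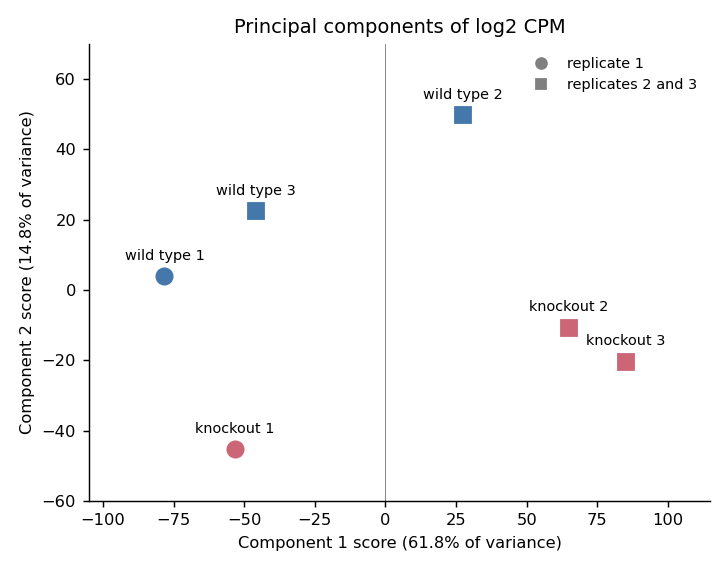
Scores of the 6 libraries on the first component (x axis, 61.8% of the variance) and the second component (y axis, 14.8%) of log2 CPM, with wild type in blue and knockout in red, circles for replicate 1 and squares for replicates 2 and 3. Wild-type replicate 2 (27.3) sits on the side of knockout replicates 2 (64.9) and 3 (85) along the first component.

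Prmt5 itself was lower in each of the 3 knockout libraries than in any wild-type library. The gene (chromosome 14, 54507182 to 54517470, mm10) stood at 37.5, 59.9 and 40.8 CPM in wild-type replicates 1 to 3 and at 14.8, 22.4 and 28.5 CPM in the knockout replicates. The means were 46.1 ± 12.1 and 21.9 ± 6.88 CPM, a 2.11-fold difference that left 47.5% of the wild-type level. The log2 fold change of -1.08 (SE 0.34) had an unadjusted p of 0.0137 and did not pass the threshold over all genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.467). In the batch-term fit it was -1.10 (SE 0.24, adjusted p = 0.0913, edgeR), with -1.32 within replicate 1 and -1.01 within replicates 2 and 3. Of the batch-term fits run, Prmt5 passed the threshold without wild-type replicate 3 (-1.30, adjusted p = 0.0236, edgeR) and with offsets for exonic length and GC content (-1.12, adjusted p = 0.0422, edgeR).

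Across the transcriptome, the knockout libraries had less of the desaturase transcript Scd1 and more of the cell cycle inhibitor transcript Cdkn1a. Svop and Plch2, both scarce in wild type, stood higher in the knockout. Scd1, which makes monounsaturated fatty acids and was the most abundant transcript in all 3 wild-type libraries, stood at 23630 ± 729 CPM in wild type and 4001 ± 736 CPM in knockout, a 5.91-fold difference. Cdkn1a, the p21 inhibitor induced by p53, stood at 71.4 ± 28.4 and 386.9 ± 100.7 CPM. In the batch-term fit 55 genes rose and 17 fell at an adjusted p under 0.05, the same counts as in the authors' deposited table. The genotype-only fit called 0 genes higher and 0 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, smallest adjusted p = 0.0668, Plch2). In that fit 1233 genes had an unadjusted p under 0.05, where chance gives 715 on average. Genes vary together, so the number in a single grouping of the libraries can lie far from that average. Whether 1233 exceeds chance was not tested. On the same genotype-only design DESeq2 called 171 genes higher and 100 lower, 68 of the 72 batch-term calls among them, and limma-voom called 0.

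All 72 batch-term calls had an unadjusted p under 0.05 in the genotype-only fit and kept their sign there and within each batch. The genotypes did not overlap for 71 of them, the exception being Vegfa. The 72 were chosen for their genotype difference in these same libraries. These agreements were therefore close to fixed by that choice and are no independent support. Over all genes, which were not so chosen, 14.5% had no overlap. Apart from ties, 10% is the mean over all splits of the libraries into 3 and 3. Genes vary together, so a single split can lie far from that mean. With genotype only, wild-type replicates 1 and 3 and knockout replicate 1 against the rest gave 5211 calls. The 14.5% is therefore no evidence for genotype either. The number of calls changed with every library left out. The batch-term fit called 29, 125 and 205 genes without wild-type replicates 1, 2 and 3. It called 21, 0 and 21 genes without knockout replicates 1, 2 and 3, and all 72 genes kept their sign in these 6 fits. Their sign there was likewise close to fixed by the choice. The batch-term fits without replicate 1 of a genotype rest on replicates 2 and 3 for the genotype difference. Replicates 2 and 3 alone gave 39 genes higher and 11 lower, and the genotype-only fit without knockout replicate 1 gave 32 and 10. Once offsets for exonic length and GC content were added, 159 genes rose and 109 fell with the batch term, so that 59.3% of 268 calls were rises, against 76.4% of the 72. At an unadjusted p under 0.05 the counts were 1728 rises and 1777 falls without the offsets and 1827 and 1575 with them.

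Genes with the most extreme log2 fold changes among the batch-term calls were named by the rule for named genes applied to that fit, a choice made after the values were seen. Svop, a synaptic vesicle protein gene, stood at 0.146 ± 0.012 CPM in wild type and 5.89 ± 2.21 CPM in knockout (log2 fold change 5.23, SE 0.52). Plch2, a phospholipase C, rose by 4.87 (SE 0.41) and Hydin, a gene of motile cilia, by 4.25 (SE 0.52). Abhd11os (chromosome 5, 135012122 to 135013157) had the smallest adjusted p, 0.00244, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, at 2.62 ± 1.14 and 50.2 ± 11.8 CPM. It overlaps Abhd11, whose own log2 fold change was 0.74 (adjusted p = 0.139, edgeR batch-term fit). The strand setting of the counting is not given in the sources used here, so the counts of this pair are uncertain. Further rises were those of Hist1h4j (3.78), Serpina3b (3.37), Pla2g2e (3.36), Disp2 (3.35), Rab26os (3.17) and Gtse1 (3.12). Hist1h4j and Serpina3b belong to families of near-identical genes, and their counts are uncertain to that extent. The largest fall was that of the prostaglandin D2 synthase gene Ptgds, by 4.49 on the log2 scale from a low level of 3.63 ± 1.93 CPM. The eotaxin receptor gene Ccr3 (-3.14) and the potassium channel gene Kcnj15 (-2.92) also fell, and the genotype-only value of Ccr3 went from -3.01 to -1.815 with length and GC offsets. Scd1 (chromosome 19, 44394450 to 44407709) fell by 2.58 (SE 0.26, adjusted p = 0.0133, edgeR batch-term fit). The engulfment adaptor gene Gulp1 fell by 2.08. The acyl-CoA synthetase gene Acsm3 (-2.05), the metal transporter gene Slc39a8 (-1.98), Cd24a (-1.95) and Csad, which acts in taurine synthesis (-1.94), also fell.

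**Figure D2:**
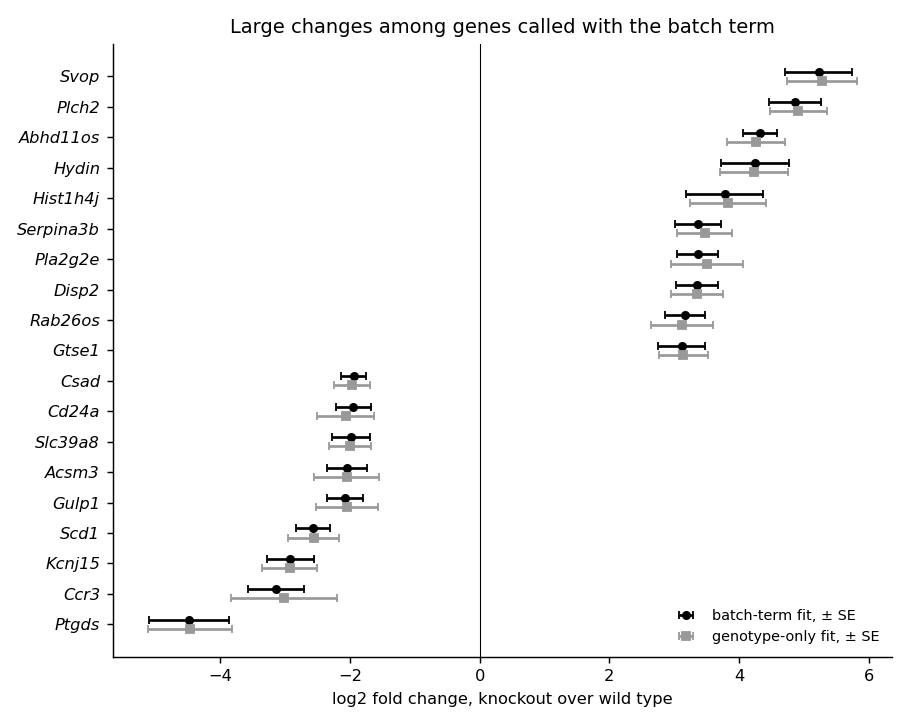
Log2 fold change, knockout over wild type (x axis), of rises and falls (y axis) named among the 72 genes called with the batch term, in the batch-term fit (black circles) and in the genotype-only fit (grey squares), with bars of 1 SE. Values run from 5.23 for Svop to -4.49 for Ptgds in the batch-term fit, and each gene has the same sign in both fits.

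Genes of fat storage moved in both directions. In the list of lipid droplet and triglyceride synthesis genes, 14 of 20 tested members lay above 0 (median log2 fold change 0.24). Cidea, which enlarges lipid droplets and is abundant in brown fat, stood at 32.0 ± 26.4 and 167.9 ± 30.5 CPM (2.39, SE 0.59). Mogat2, a monoacylglycerol acyltransferase, stood at 9.20 ± 6.81 and 47.9 ± 31.3 CPM and Plin5 at 14.7 ± 4.11 and 29.4 ± 9.16 CPM. Plin4, a coat protein of lipid droplets, stood at 2582 ± 641 and 1017 ± 138 CPM (-1.34, SE 0.34). In the batch-term fit Mogat2 rose (2.44, adjusted p = 0.0321, edgeR) and Plin4 fell (-1.33, adjusted p = 0.0468, edgeR). In the genotype-only fit 0 members passed over all genes, while Cidea and Plin4 passed adjusted over the list alone, as did 7 higher and 2 lower in the batch-term fit. Camera called the list higher (adjusted p = 0.0375, and adjusted p = 0.52 with an estimated correlation). The call was lost without knockout replicate 3 (0.0751) and with length and GC offsets (0.696).

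Among 17 genes of de novo fatty acid synthesis, Scd1 passed adjusted over the list alone (adjusted p = 0.00369, edgeR) and 0 passed over all genes in the genotype-only fit, against 2 lower over the list alone in the batch-term fit. The malic enzyme gene Me1 stood at 943.9 ± 285.2 and 406.1 ± 48.7 CPM. The elongase genes stood lower too, Elovl5 at 128.1 ± 1.65 and 78.1 ± 22.8 CPM and Elovl6 at 223.9 ± 105.3 and 122.9 ± 36.3 CPM, and neither passed. The fatty acid synthase gene Fasn stood at 6053 ± 1931 and 6757 ± 4624 CPM (adjusted p = 0.894, edgeR). Its regulator Srebf1 stood at 252.9 ± 47.2 and 198.5 ± 43.2 CPM (adjusted p = 0.64, edgeR). Of the 17 genes, 10 lay above 0, with a median of 0.02 and a mean of -0.24. The list's camera direction was lower (adjusted p = 0.0533), so it was not called. With an estimated correlation its adjusted p was 0.599. With length and GC offsets it was called lower, without the batch term (adjusted p = 0.00481, 0.467 with an estimated correlation) and with it (adjusted p = 0.00307, 0.558 with an estimated correlation).

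Genes of cholesterol synthesis and uptake were higher as a list, with 18 of 24 members above 0 and a median of 0.43 (camera adjusted p = 0.000595, adjusted p = 0.358 with an estimated correlation). The squalene epoxidase gene Sqle stood at 11.4 ± 0.90 and 25.9 ± 5.08 CPM. Dhcr7 stood at 21.9 ± 10.3 and 58.8 ± 21.8 CPM and Fdft1 at 60.2 ± 15.9 and 127.6 ± 54.9 CPM. In the genotype-only fit 2 members, Sqle among them, passed adjusted over the list alone and 0 over all genes, and in the batch-term fit 9 passed higher over the list alone.

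Mature adipocyte markers were not called as a list (median -0.07, 10 of 20 above 0, camera adjusted p = 0.372, adjusted p = 0.599 with an estimated correlation). With length and GC offsets the adjusted p was 0.0575, and with these offsets and the batch term the list was called lower (adjusted p = 0.0167, adjusted p = 0.59 with an estimated correlation). The adiponectin gene Adipoq stood at 3933 ± 433 and 4606 ± 1122 CPM (log2 fold change 0.23, 0.078 to 0.41 with a library left out, and -0.0065 with length and GC offsets). The leptin gene Lep stood at 845.9 ± 263.8 and 581.1 ± 202.0 CPM. Pparg, the master regulator of adipocyte differentiation, stood at 190.1 ± 20.7 and 126.5 ± 30.5 CPM (-0.59, and -0.22 with length and GC offsets). Fabp4 stood at 15250 ± 2478 and 11340 ± 2165 CPM (-0.43, and -0.13 with these offsets). With a library left out its log2 fold change was -0.56 to -0.28 with genotype only and -0.61 to -0.22 with the batch term. Plin1 stood at 1214 ± 455 and 1493 ± 16.9 CPM (0.30, 0.090 to 0.64 with a library left out, and -0.072 with length and GC offsets). The seipin gene Bscl2 stood at 436.3 ± 170.5 and 802.5 ± 377.2 CPM (0.88, SE 0.47, adjusted p = 0.593, edgeR). The adipsin gene Cfd had the smallest p of the list at 13580 ± 2664 and 5519 ± 1124 CPM (-1.30, SE 0.39, adjusted p = 0.418, edgeR), followed by Pparg, Acsl1 (-0.86) and Cd36 (-0.85, and -0.088 with the offsets). Adjusted over the list alone 0 of the adipocyte markers passed in the genotype-only fit, with 0 over all genes. In the batch-term fit 4 passed lower over the list alone, Cfd, Acsl1 and Cd36 among them, and 1 passed higher.

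Brown and beige fat markers were higher in the knockout, with 13 of 15 above 0 and a median log2 fold change of 1.18 (camera adjusted p = 5.01e-05, adjusted p = 0.358 with an estimated correlation). Kcnk3, a potassium channel gene of thermogenic fat, stood at 52.9 ± 6.82 and 194.1 ± 55.5 CPM and rose in the batch-term fit (1.85, SE 0.21, adjusted p = 0.0183, edgeR). Cox7a1 stood at 15.1 ± 8.80 and 48.0 ± 13.8 CPM and Cox8b at 85.0 ± 33.7 and 205.4 ± 68.4 CPM. The uncoupling protein gene Ucp1 varied widely within each genotype, at 34.4 ± 47.1 and 163.8 ± 103.4 CPM (2.25, SE 1.38, adjusted p = 0.606, edgeR). Its value rested on single libraries: it was 1.25 in replicates 2 and 3 alone, and 5.76 and called (adjusted p = 0.0151, edgeR) in the batch-term fit without wild-type replicate 3. Kcnk3, Cidea and Cox7a1, 3 members, passed adjusted over the list alone and 0 over all genes in the genotype-only fit. In the batch-term fit 5 members passed higher over the list alone and 2 passed lower, Ebf2 and Tmem26, which are named after their values were seen.

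Nuclear-encoded genes of oxidative phosphorylation lay above 0 for 35 of 41 members by a small amount each (median 0.49, camera adjusted p = 0.000221, adjusted p = 0.599 with an estimated correlation). With length and GC offsets the median was 0.23 and the list was still called (adjusted p = 0.0022, 0.598 with an estimated correlation). None passed singly, with 0 members over all genes and 0 adjusted over the list alone in either fit. Uqcrc1 stood at 278.8 ± 46.0 and 491.0 ± 187.2 CPM and Cyc1 at 268.4 ± 67.1 and 457.4 ± 177.6 CPM. The complex I gene Ndufs3 stood at 144.2 ± 42.1 and 241.7 ± 93.7 CPM. Replicate 1 of each genotype had the lowest mean log2 CPM of the list, 7.65 against 8.36 and 8.26 in wild type and 7.93 against 8.80 and 8.71 in knockout. Without wild-type replicate 1 the list was not called (adjusted p = 0.0745). Fatty acid oxidation genes lay above 0 for 16 of 20 members (median 0.26, camera adjusted p = 0.0385, adjusted p = 0.553 with an estimated correlation). Acaa2 (0.94), Etfb (1.11, and 0.59 with length and GC offsets), Cpt2 (0.71, and 0.47 with the offsets) and Hadha (0.61) had the smallest p. In the genotype-only fit 0 members passed over all genes or adjusted over the list alone, and in the batch-term fit 2, Acaa2 and Etfb, passed over the list alone. That call held in 2 of 6 fits with a library left out. It was lost without wild-type replicates 2 (0.0571) and 3 (0.0598) and knockout replicates 1 (0.0759) and 2 (0.198).

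Targets of p53 and genes of the cell cycle were both called higher. Of 20 p53 targets 12 lay above 0 (median 0.49, camera adjusted p = 0.00598, adjusted p = 0.358 with an estimated correlation). Cdkn1a rose in the batch-term fit (2.45, SE 0.25, adjusted p = 0.0134, edgeR). Phlda3, a p53-induced inhibitor of AKT, stood at 229.5 ± 30.4 and 539.1 ± 184.4 CPM. Aen stood at 19.8 ± 1.78 and 35.0 ± 2.57 CPM and the death receptor gene Tnfrsf10b at 7.68 ± 1.18 and 15.1 ± 2.99 CPM. In the genotype-only fit 1 target, Cdkn1a, passed adjusted over the list alone and 0 over all genes, and in the batch-term fit 7 passed higher over the list alone. The list was not called without wild-type replicate 2 (0.0571) or knockout replicate 1 (0.32). Its mean log2 CPM overlapped between genotypes, at 4.55, 4.26 and 4.57 in wild-type replicates 1 to 3 and 5.21, 4.75 and 4.48 in the knockout replicates. Of 20 cell cycle genes 19 lay above 0 (median 0.49, camera adjusted p = 0.000221, adjusted p = 0.358 with an estimated correlation). These genes had low levels, and 0 passed over all genes or adjusted over the list alone in the genotype-only fit, against 3 higher over the list alone in the batch-term fit. Mcm5, a subunit of the replicative helicase, stood at 7.85 ± 2.88 and 21.6 ± 6.63 CPM and Cdk1 at 4.004 ± 0.781 and 9.52 ± 2.04 CPM. Birc5 stood at 2.13 ± 0.67 and 5.53 ± 0.80 CPM and Aurkb at 2.41 ± 0.40 and 4.68 ± 0.35 CPM.

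T and natural killer cell markers lay above 0 for all 17 tested members, with a median log2 fold change of 1.68 (camera adjusted p = 3.74e-08, adjusted p = 0.433 with an estimated correlation). Singly, 0 members passed over all genes or adjusted over the list alone in the genotype-only fit, while 14 passed higher over the list alone and 0 over all genes in the batch-term fit. Their mean log2 CPM was 0.29, 0.92 and 0.65 in wild-type replicates 1 to 3 and 1.67, 1.36 and 2.79 in the knockout replicates. B and plasma cell markers, which were not called, had means of 1.529, 2.626 and 1.499 and of 0.58, 1.69 and 3.03, highest in the same library of each genotype as the T and natural killer cell markers. Lck stood at 3.42 ± 0.97 and 13.7 ± 11.6 CPM and Nkg7 at 2.90 ± 0.92 and 13.3 ± 11.9 CPM. Cd3e stood at 2.58 ± 0.53 and 7.09 ± 3.59 CPM and Cd8b1 at 1.04 ± 0.57 and 4.53 ± 2.84 CPM.

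Cytokine and chemokine genes were called higher as a list, with 14 of 18 above 0 (median 0.41, camera adjusted p = 0.00141, adjusted p = 0.52 with an estimated correlation). The list's mean log2 CPM overlapped between genotypes. It was 1.54, 2.69 and 1.95 in wild-type replicates 1 to 3 and 2.73, 2.50 and 2.81 in the knockout replicates. The acute-phase gene Saa3 stood at 10.9 ± 1.81 and 68.5 ± 24.2 CPM and rose in the batch-term fit (2.62, adjusted p = 0.019, edgeR). The T cell attractant gene Cxcl9, at 43.5 ± 12.9 and 143.4 ± 30.5 CPM, also rose there (1.75, adjusted p = 0.0267, edgeR). Ccl5 stood at 8.19 ± 5.02 and 56.1 ± 49.6 CPM and Cxcl10 at 2.80 ± 0.82 and 7.11 ± 1.55 CPM. These 4 genes passed adjusted over the list alone in the genotype-only fit, where 0 passed over all genes. Over the list alone 5 passed higher and 1 lower in the batch-term fit. Tnf (1.15 ± 0.93 and 1.31 ± 0.66 CPM) and Ccl2 (5.13 ± 3.47 and 5.65 ± 2.56 CPM) differed by less than the spread between libraries.

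General macrophage markers were not called (13 of 18 above 0, median 0.58, camera adjusted p = 0.0737), and their members moved apart. Adgre1, which encodes F4/80, stood at 56.5 ± 8.04 and 70.2 ± 11.1 CPM and Cd68 at 43.2 ± 18.8 and 85.1 ± 8.29 CPM. Ctss stood at 72.5 ± 8.99 and 136.5 ± 43.3 CPM and Laptm5 at 125.0 ± 43.9 and 244.8 ± 85.0 CPM. Cd163, the haemoglobin scavenger receptor of resident macrophages, stood at 139.2 ± 33.8 and 50.8 ± 14.1 CPM and fell in the batch-term fit (-1.47, SE 0.20, adjusted p = 0.0321, edgeR). In the genotype-only fit it was the 1 member to pass adjusted over the list alone, with 0 over all genes. Over the list alone 8 passed higher and 3 lower in the batch-term fit. Lipid-associated macrophage markers, genes of macrophages that take up lipid, were higher as a list, with 12 of 13 above 0 and a median of 0.63 (camera adjusted p = 0.000327, adjusted p = 0.358 with an estimated correlation). Itgax stood at 6.46 ± 0.81 and 19.6 ± 11.2 CPM and Gpnmb at 19.9 ± 8.33 and 63.2 ± 42.5 CPM. Atp6v0d2 (log2 fold change 2.33) and Dcstamp (2.22) had lower levels. Atp6v0d2 stood at 34.4 CPM in knockout replicate 1 against 7.20 and 5.79 CPM in the other knockout libraries. In replicates 2 and 3 alone the values were 1.04 and 1.30. Of the list 0 members passed over all genes or adjusted over the list alone in the genotype-only fit, and 6 passed higher over the list alone in the batch-term fit.

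**Figure D3:**
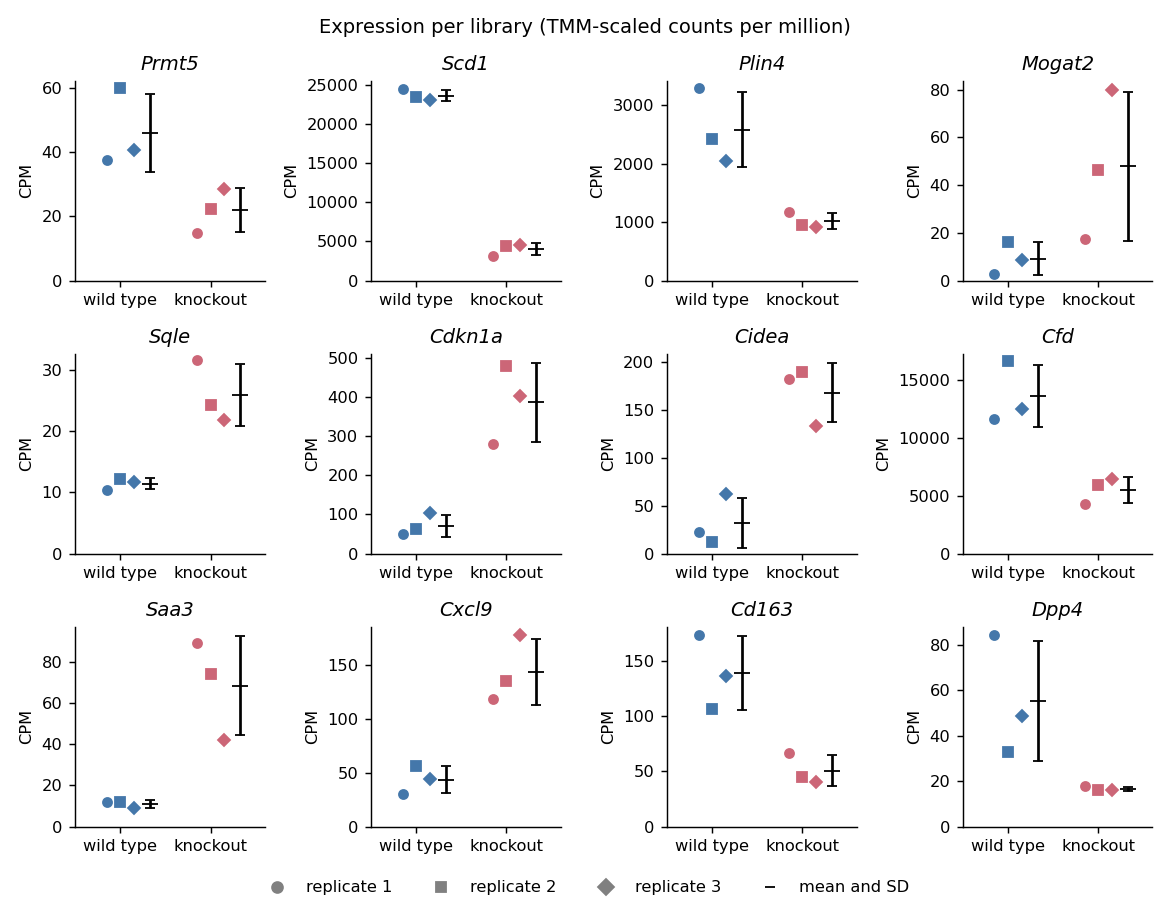
TMM-scaled CPM (y axis, linear, from 0) of 12 genes in each wild-type (blue) and knockout (red) library, with circles, squares and diamonds for replicates 1, 2 and 3 and the mean with SD beside them. Scd1 falls from 23630 to 4001 CPM on average and Cdkn1a stands at 71.4 and 386.9 CPM. The genotypes do not overlap in any of the 12 panels. The 12 were picked from the named genes and do not stand for all of them, since Vegfa and Ucp1, for example, overlap.

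Of 19 adipose progenitor and fibroblast markers only 3 lay above 0 (median -0.65, camera lower, adjusted p = 0.000221, adjusted p = 0.358 with an estimated correlation). Dpp4, a marker of early progenitors, stood at 55.4 ± 26.5 and 16.6 ± 0.93 CPM and the matrix proteoglycan gene Dcn at 1459 ± 318 and 577.4 ± 64.0 CPM. These 2 genes passed adjusted over the list alone (adjusted p = 0.0285 each, edgeR), with 0 over all genes, in the genotype-only fit, against 9 lower and 1 higher over the list alone in the batch-term fit. With length and GC offsets the log2 fold change of Dpp4 went from -1.74 to -0.96 and that of Dcn from -1.34 to -0.80. Fbn1 stood at 273.6 ± 93.3 and 127.5 ± 23.9 CPM and Anxa3 at 102.7 ± 10.3 and 59.7 ± 7.76 CPM. Without knockout replicate 1 the list's adjusted p was 0.0511. Mesothelial markers were called lower (median -0.45, 3 of 10 above 0, camera adjusted p = 0.0185, adjusted p = 0.599 with an estimated correlation). Gpm6a (35.1 ± 12.3 and 12.2 ± 2.19 CPM) was the 1 member to pass adjusted over the list alone in either fit, with 0 over all genes, and its log2 fold change went from -1.53 to -0.38 with length and GC offsets. Lrrn4 (-1.05), Wt1 (-0.70) and Rspo1 (-0.55, and -1.06 with the offsets) did not pass. Knockout replicate 1 had a mean log2 CPM of 3.04 over the list, against 4.59 and 4.996 in the other knockout libraries. The call was lost without that library (0.996) and without wild-type replicate 2 (0.0904).

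Smooth muscle and pericyte markers were called higher (8 of 13 above 0, median 0.47, camera adjusted p = 0.0359, adjusted p = 0.599 with an estimated correlation). Tagln stood at 398.3 ± 52.3 and 1028 ± 307 CPM and the pericyte gene Cspg4 at 39.7 ± 5.79 and 87.1 ± 18.1 CPM. Cnn1 stood at 61.6 ± 8.86 and 192.6 ± 129.3 CPM, and these 3 genes passed adjusted over the list alone with 0 over all genes in the genotype-only fit. With the batch term 3 passed higher and 1 lower over the list alone. Acta2 stood at 378.0 ± 103.3 and 832.7 ± 346.6 CPM. The call was lost without wild-type replicates 2 (0.278) and 3 (0.0656), without knockout replicate 3 (0.14), with the batch term (0.0901) and with length and GC offsets (0.0752). Immediate-early genes, which respond within minutes to stress and handling, were called lower (5 of 17 above 0, median -0.34, camera adjusted p = 0.0488, adjusted p = 0.52 with an estimated correlation). Egr1 stood at 51.6 ± 37.1 and 16.3 ± 2.41 CPM and Fos at 26.9 ± 22.3 and 9.32 ± 1.32 CPM. Nr4a1 stood at 16.01 ± 8.88 and 6.79 ± 1.54 CPM and Klf4 at 72.0 ± 27.2 and 37.3 ± 22.7 CPM. Of the list 0 genes passed over all genes or adjusted over the list alone in the genotype-only fit, and 1, Klf4, passed lower over the list alone in the batch-term fit. The call was lost without wild-type replicates 1 (0.158) and 2 (0.0904), without knockout replicate 1 (0.32), with RLE size factors (0.0516) and with the batch term (0.0537). It was stronger with length and GC offsets, without the batch term (4.98e-05, 0.467 with an estimated correlation) and with it (4.63e-05, 0.536 with an estimated correlation).

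The hypoxia response list was not called (6 of 15 above 0, median -0.08, camera adjusted p = 0.41), although single members stood apart. Vegfa, which encodes the vascular endothelial growth factor, was at 202.5 ± 108.1 and 71.4 ± 58.1 CPM and fell in the batch-term fit (-1.68, SE 0.24, adjusted p = 0.0361, edgeR). Pdk1 was at 61.3 ± 12.6 and 26.8 ± 9.98 CPM and Bnip3 at 578.7 ± 54.3 and 322.5 ± 92.7 CPM. Pfkfb4 was at 11.9 ± 1.85 and 23.1 ± 4.14 CPM, and 0 members passed over all genes or adjusted over the list alone in the genotype-only fit, against 3 lower and 1 higher over the list alone in the batch-term fit. PRMT5 partners and the other arginine methyltransferases did not differ as a list (7 of 11 above 0, median 0.17, camera adjusted p = 0.423). Prmt1 stood at 54.4 ± 9.15 and 81.6 ± 31.0 CPM and Prmt7 at 21.3 ± 5.76 and 33.2 ± 12.3 CPM. Coprs stood at 13.2 ± 6.42 and 19.8 ± 7.84 CPM and Riok1 at 16.9 ± 1.94 and 12.1 ± 4.54 CPM.

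The other lists were not called by camera in the genotype-only fit. Their adjusted p-values were 0.355 for lipolysis, 0.0737 for insulin signalling, 0.0533 for spliceosome Sm and snRNP assembly genes, 0.372 for the unfolded protein and integrated stress response, and 0.835 for interferon-stimulated genes. Among cell type markers they were 0.932 for B and plasma cell markers, 0.656 for dendritic cell, neutrophil and mast cell markers, 0.316 for endothelial markers, 0.372 for skeletal muscle markers and 0.913 for nerve and Schwann cell markers. They were 0.748 for extracellular matrix genes, 0.16 for circadian clock genes, 0.349 for neighbours of Prmt5 and 0.372 for neighbours of Adipoq. Endothelial markers (6 of 15 above 0, median -0.12) were called lower with length and GC offsets, without the batch term (0.0427) and with it (0.0223), and not with an estimated correlation (0.467 and 0.536). Col1a1, in the extracellular matrix list, stood at 443.3 ± 270.1 and 388.9 ± 57.7 CPM. Over all 33 lists tested, 11 were called higher and 3 lower with the preset correlation of 0.01 and 0 with an estimated correlation. With the batch term the numbers were again 11 and 3, but smooth muscle and immediate-early genes were replaced by spliceosome genes (higher, adjusted p = 0.0244) and insulin signalling genes (lower, adjusted p = 0.0244). With an estimated correlation and the batch term both had an adjusted p = 0.59, and 0 lists were called. The interferon list had a median of 0.07, a mean of -0.07 and a test direction lower, and it and de novo fatty acid synthesis were the 2 lists in which median and test differed in sign. Skeletal muscle markers had a mean log2 CPM of 6.77, 0.04 and 7.83 in wild-type replicates 1 to 3 and 4.12, 4.11 and 6.52 in the knockout replicates.

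**Figure D4:**
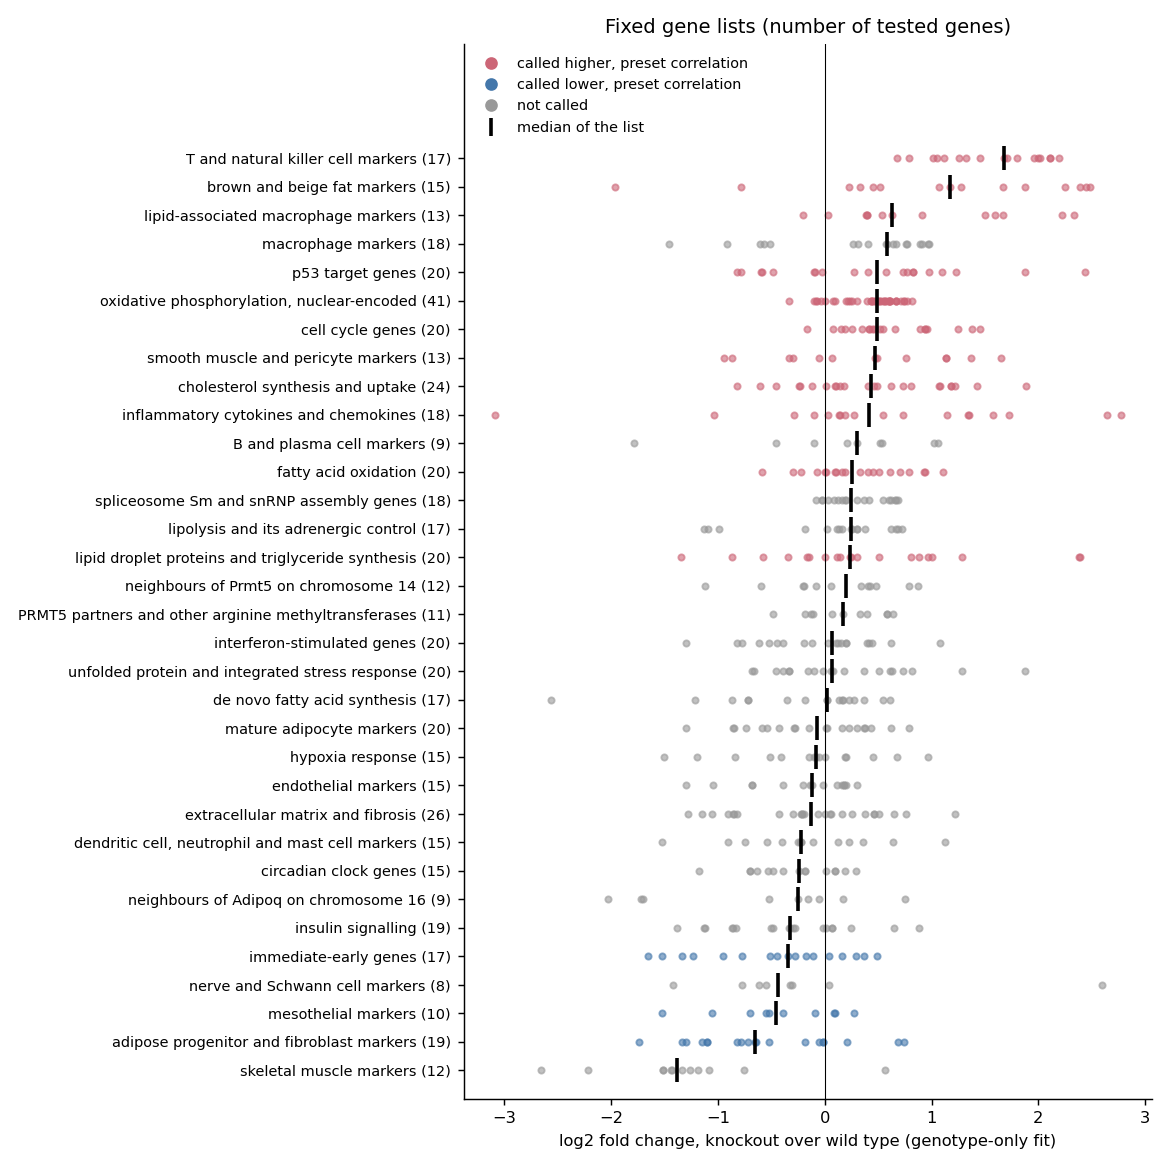
Log2 fold change, knockout over wild type in the genotype-only fit (x axis), of each tested gene (points) of the 33 fixed lists (y axis, number of tested genes in brackets), with the median of each list as a black bar. Medians run from 1.68 for T and natural killer cell markers to -1.38 for skeletal muscle markers, and colour marks the 11 lists called higher and the 3 called lower with the preset correlation, 0 of which were called with an estimated correlation.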

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

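The batch term, the batch term with libraries left out, replicates 2 and 3 alone and the length and GC offsets were chosen after the data were seen, and the other settings were planned. Against 0 genes higher and 0 lower with genotype only, RLE size factors gave 1 and 0, DESeq2 171 and 100, the replicate block 40 and 17, and the batch term 55 and 17. Replicates 2 and 3 alone gave 39 and 11, length and GC offsets 7 and 2, those offsets with the batch term 159 and 109, and an adjusted p under 0.1 gave 3 and 0. The strict filter, limma-voom and the 2-fold threshold left 0 and 0, no filter removed the same 0 genes, and a pseudocount was not run because the values are counts. Over the fits with a library left out, with and without the batch term, the counts ran from 0 to 111 higher and from 0 to 94 lower. Same-numbered libraries deviated together in replicates 1 and 2 (correlations across genes 0.64 and 0.53) but not 3 (-0.1), and wild-type replicate 3 correlated best with knockout replicate 1 (0.16), so the numbers were not taken to pair the libraries. Prmt5 kept its direction under every setting run, between -0.84 and -1.31 with a library left out and -1.10 under the replicate block (adjusted p = 0.153, edgeR), and passed the threshold with offsets and the batch term (-1.12). The 11 lists higher and 3 lower became 0 and 0 with an estimated correlation, with fry, and with an estimated correlation together with the batch term, the offsets or both. The lists higher ran from 9 to 11 and those lower from 2 to 6 with a library left out, 6 being without knockout replicate 3, the offsets gave 5 lower and the offsets with the batch term 6. Under the replicate block 11 and 3 lists were called, with smooth muscle and pericyte markers (0.0646) and immediate-early genes (0.0601) no longer among them. Of 106 named genes besides Prmt5, 6 changed sign somewhere, 0 of them called in the setting concerned. They were Adipoq (-0.0065 with offsets, -0.0014 with offsets and the batch term), Plin1 (-0.072 with offsets), Fasn (-0.0044 under the replicate block, -0.020 with offsets, -0.57 to 0.44 with a library left out), Tnf (-0.057 in replicates 2 and 3 alone, -0.27 to 1.10 with a library left out), Ccl2 (-0.68 and -0.68 to 0.79) and Col1a1 (0.30 and -0.46 to 0.43). The causes of these changes were not tested. The other named genes kept their direction. With offsets 28 of the 106 changed their log2 fold change by over 1.5 times, 24 towards or past 0 and 4 away from it. Besides those given with the genes, they were Plin5 (1.00 to 0.63), Elovl6 (-0.87 to -0.53), Srebf1 (-0.35 to -0.66), Uqcrc1 (0.82 to 0.42), Cyc1 (0.77 to 0.18), Ndufs3 (0.75 to 0.48), Phlda3 (1.23 to 0.73), Aen (0.82 to 0.53), Adgre1 (0.31 to 0.51), Ccl2 (0.14 to 0.36), Tnf (0.19 to 0.031), Prmt1 (0.58 to 0.16), Coprs (0.58 to 0.14) and Riok1 (-0.49 to -0.075), among others. With 3 libraries per genotype, simulated 2-fold changes were recovered for 4% of genes with genotype only and 28% with the batch term. Most changes of that size were thus missed in either simulation. Each simulation used the dispersions of its own fit and held no batch effect, so these shares do not rank the fits on the real libraries.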

Other observations

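The families and genes of the first paragraph, the batch and genotype tests on the first component and the test of muscle marker correlation were chosen after the result was seen. Among the 72 genes called with the batch term were 3 of 23 histone genes taken by symbol (Hist, a number, then h), all of histone H4. The libraries were enriched for polyA RNA, so these counts need not follow the total RNA of the histone genes. Hist1h4h stood at 47.4 ± 20.4 CPM in wild type and 148.1 ± 61.4 CPM in knockout and Hist1h4c at 1.16 ± 0.19 and 7.83 ± 3.17 CPM. Of the 23, 21 lay above 0 in the batch-term fit (median log2 fold change 1.00 in both fits, 1.01 with RLE size factors and 0.98 with length and GC offsets and the batch term). Small nucleolar RNA host genes held 3 rises among 14 tested, Snhg3 (1.73), Snhg10 (2.41) and Snhg8 (1.19), with 7 of 14 above 0. Potassium channel genes held 4 calls among 46, the rises of Kcnh2 (2.70), Kcnj14 (2.06) and Kcnk3 and the fall of Kcnj15, with 22 of 46 above 0. The families were picked because they were seen among the calls, so a test of their share of the calls would only restate that choice and none is reported, and histone H4 genes share near-identical sequence.

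The genes of this paragraph were each chosen after their values were seen, and those from Ret to Gpt were batch-term calls. Ret, the receptor of glial-derived neurotrophic factors, stood at 18.8 ± 11.0 and 84.6 ± 15.2 CPM and the low-affinity nerve growth factor receptor gene Ngfr at 8.30 ± 4.33 and 40.0 ± 25.3 CPM. S100b, which adipocytes also express, stood at 4.92 ± 0.93 and 29.8 ± 13.9 CPM and the adrenergic receptor gene Adra1d at 7.44 ± 0.94 and 23.2 ± 3.51 CPM. These 4 genes rose. Nerve and Schwann cell markers, S100b among them, were not called as a list, with 2 of 8 above 0 and a median of -0.43. Gldc of glycine breakdown differed little within each genotype (1.85 ± 0.26 and 10.8 ± 0.18 CPM). Ifi27l2a rose from 1106 ± 605 to 5409 ± 2557 CPM, and the alanine transaminase gene Gpt fell (171.3 ± 47.5 and 51.8 ± 6.64 CPM). Xist, the RNA of the inactive X chromosome, was counted in every library, at 958.1, 106.1 and 509.7 CPM in wild-type replicates 1 to 3 and 1044, 45.6 and 47.2 CPM in the knockout replicates. An epididymal depot implies male animals, in which Xist is not expected at such levels. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were looked up and are not among the 14291 genes analysed here. Genes of low expression had been left out, and the least third-highest CPM of a gene kept was 0.606. Xist in every library and the absence of these Y-linked genes argue against male animals, and thereby against the epididymal label. The authors' filter is not known in full, so the sex of the animals was not settled. The nuclear RNA Malat1 was counted at 1301, 117.3 and 395.3 and at 1544, 48.9 and 58.3 CPM. The liver gene Alb was counted at 48.4, 326.7 and 123.9 and at 10.8, 86.3 and 24.8 CPM.

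The split of the libraries along the first component, which sets wild-type replicates 1 and 3 and knockout replicate 1 apart from the rest, was weighed against 3 explanations. Genotype explained 26.8% of the variance of the scores, too little to be the whole cause. A trend with exonic length and GC content remains open: gene loadings had Spearman correlations across genes of -0.492 with length and 0.567 with GC content, and removing each library's trend lowered the variance along the component by 47.1%, between the bounds set for and against it. The batch of the authors' fit explained 55.8%, also between its bounds. Wild-type replicate 3, which is outside the batch of replicate 1, lies with it, which counts against the batch as the whole cause, but a single library does not exclude it.

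Skeletal muscle markers differed between libraries by up to 7.79 on the log2 scale. Ckm stood at 82.7, 0.156 and 194.2 CPM in wild-type replicates 1 to 3 and at 9.28, 10.6 and 111.3 CPM in the knockout replicates, and Myh4 at 105.3, 0 and 299.7 and at 4.50, 7.79 and 129.2 CPM. Pieces of skeletal muscle in some samples may account for this, since the 12 markers, 0 of them in another list, moved together with a median pairwise correlation of 0.918 over the 6 libraries. Acta1 departed from this pattern, at 140.1 CPM in wild-type replicate 2 and 1007 CPM in knockout replicate 2, and no biological explanation was tested. The tables argue against a trend with exonic length and GC content as the cause, because the fall of the range once the trend was removed was -2.62%, from 7.79 to 8.

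More genes rose than fell with the batch term, 55 against 17, and the rises were short, with a median exonic length of 1835 bases against 3727 for the falls and 2883 for all genes. A trend with exonic length and GC content remains open as an explanation of this imbalance. With the trend removed the share of rises was 59.3% in place of 76.4%, under the bound of 60% set before. That fall came from more falls being called, 109 in place of 17, while the rises called went from 55 to 159, so the share does not decide. Removing the modelled trend left most of the calls in place. With the offsets and the batch term together, 52 of the 55 rises and 14 of the 17 falls were still called. The 72 had been chosen for their genotype difference in these libraries, and the fit with offsets called 268 genes. Their staying called therefore does not decide how far the trend shaped them. No biological explanation of the imbalance was tested.

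Splits of the 6 libraries were too few to give a share under 0.05. With genotype only, 10 of the 10 splits into 3 and 3 gave at least as many genes as the real one, 0. Since no split can call fewer than 0, this outcome was fixed in advance and decides nothing. The highest other gave 5211, setting wild-type replicates 1 and 3 and knockout replicate 1 against the rest, which points to the structure of the samples along the first component. With the batch term, 1 of the 6 splits that keep the batches, the real one, gave as many as 72 genes and the highest other gave 0. For the lists, 3 of the 10 splits gave as many calls as the real 14, and the highest other gave 15.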
